A study of Prochlorococcus sp. MIT 0604 with 9 samples.

How the data were processed

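Prochlorococcus MIT0604, a marine picocyanobacterium, was profiled by strand-specific RNA sequencing in 3 groups of 3 cultures: untreated controls, cultures given mitomycin C at 15 µg per mL for 2 h, and cultures given a UV shock of 30 s at 254 nm and 100 µW per square cm. The time between the UV shock and the harvest is not given in the sources used here. The series design states that the replicates were separate cultures, so the p-values measure the spread between cultures. Per the labels' protocols, RNA was extracted with a small-RNA column kit, depleted of ribosomal RNA and made into libraries with a kit that keeps the strand. The labels name the molecule genomic DNA, although their own extraction protocol is for RNA, and the values were treated as RNA throughout.

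The authors counted reads per gene, and the deposited counts are whole numbers that have not been normalized. There are 72 count files, 4 sequencing lanes for each of 9 libraries on each strand, and each holds 2047 genes. Per the submitters' processing notes, BWA, HTSeq 0.11.2 and DESeq2 1.24.0 were used. The version of BWA, the genome build and the treatment of reads that map to several places are not given in the sources used here, and the files list 0 reads as not uniquely aligned. No feature of the files is a ribosomal or transfer RNA. Gene products and start and end positions in bp (other values in the deposited tables, with no chromosome, strand or build named) matched all 2047 genes, of which 745 are called hypothetical proteins. The authors also deposited DESeq2 tables for the 3 comparisons on each strand, which hold a mean of normalized counts (a signal averaged over all samples), a log2 fold change with its standard error, and a p-value before and after adjustment. The signal column was not used in any comparison, while the deposited log2 values and adjusted p-values were set beside the fits made here.

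Lanes of a library were summed. For 54 pairs of lanes of a library the chi-square per degree of freedom lay between 0.949 and 1.09, as sampling noise gives, whereas for the 9 pairs of replicate libraries within a group it lay between 7.51 and 135, so no library was a copy of another in its group. Pairs from different groups were not compared. Lines of the count files that name no gene stayed out of the library sizes and tests. Reads outside genes made up 15.2% ± 0.338 of the aligned reads in the controls, 10.5% ± 0.827 with mitomycin C and 14.2% ± 0.465 with UV (SD, n = 3). Reads falling on more than 1 gene made up 2.30% ± 0.214, 3.39% ± 0.0324 and 2.46% ± 0.0913 of aligned reads in the same order, and 2.53% ± 0.127, 1.89% ± 0.134 and 3.48% ± 0.891 of reads were not aligned. The sense files hold more reads than the antisense files of the same library, by 3.89% to 5.36% of the reads in the sense files. That difference was not analysed here. The share of reads outside genes draws on both files, as reads on no gene in the sense file less the antisense reads on genes, so it carries that difference.

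Sense totals ran from 5095136 counts in UV replicate 1 to 11046942 in control replicate 2. A count of 0 in a library allows up to 3 counts, or 0.272 to 0.589 CPM of the sense total. Binomial intervals (Wilson, 95%) and this floor cover counting error alone, because the reads carry no molecular identifiers. The other 7 sense totals were 6056261 and 5603426 for control replicates 1 and 3, 5653763, 5514682 and 5910196 for mitomycin C, and 5845354 and 7277058 for UV replicates 2 and 3. Antisense totals ran from 371081 in control replicate 1 to 1612907 in mitomycin C replicate 3.

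The count test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on all 9 libraries with group as the sole term (6 residual degrees of freedom), TMM scaling and a filter on low counts with a minimum of 10 counts. It tested 2033 genes in sense and 1979 in antisense, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. TMM factors were 0.725 to 0.920 for the controls, 1.27 to 1.37 for mitomycin C and 0.883 to 0.957 for UV in sense. The biological coefficient of variation was 13.3% in sense and 12.4% in antisense. Levels are given in CPM, counts scaled to the TMM-scaled library size, and log2 fold changes come with the standard error of the fit. Antisense counts were fitted separately with their own totals, so antisense fold changes are relative to the other antisense counts.

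Gene lists were taken by symbol or product: DNA repair and SOS, mobile elements and phage-like genes, photosystem II, photosystem I, cytochrome b6f and electron transport, antenna and chlorophyll synthesis, high light inducible proteins, ATP synthase, carbon fixation and carboxysome, pentose phosphate pathway and glycogen, ribosomal proteins, chaperones and proteases, sigma factors and transcription, oxidative stress, replication and cell division, nitrogen assimilation, phosphate acquisition, iron and metal, and circadian clock. The phosphate list takes every porin, and the mobile element list every integrase or site-specific recombinase. Of these 19 lists, 18 held at least 5 tested genes and were tested with camera (limma 3.58.1, correlation between genes set to 0.01). Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each sense comparison, the 8 largest increases and the 8 largest decreases past the threshold whose 3 libraries of a group all lay beyond the 3 of the other. It added up to 3 members past the threshold per list, and recA, lexA, umuC, umuD, uvrA, ftsZ and psbA whatever their result. The antisense comparisons named the 3 largest in each direction, and the shared response 5 in each direction. No gene matched umuC by name, and the name match was widened to find uvrA and psbA once the product names had been seen.

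Shares of reads per library were compared by an exact two-sided permutation test over 20 arrangements of 3 against 3 libraries, whose smallest p is 0.1. The arrangements took no account of replicate numbers. The overlap of the responses was set beside 50 simulations in which all 9 libraries were drawn independently from the control means and both unchanged treated groups shared the 3 simulated controls.

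The test was checked on simulated counts with 200 changed genes per comparison. In sense it recovered 62.7%, 59.7% and 62.7% of genes changed 1.5-fold, 91.0%, 88.1% and 92.5% of those changed 2-fold, and 100% of those changed 4-fold, for mitomycin C against control, UV against control and mitomycin C against UV in turn. Between 2.37% and 4.52% of its calls were false. In antisense it recovered 49.3%, 44.8% and 56.7% at 1.5-fold, 91.0%, 74.6% and 92.5% at 2-fold, and 97.0%, 95.5% and 95.5% at 4-fold, with 3.07% to 5.78% of calls false. For mitomycin C against control the list test called the 1 list that was changed and 0 of 17 that were not. In these simulations genes varied independently of each other and most were unchanged. Real list members varied together, with an estimated correlation of 0.711 in the pentose phosphate list for mitomycin C against control. Most genes also passed with mitomycin C, so these rates may not carry over.

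Replicate numbers are shared by the groups in the labels, which do not say what a number stands for. In sense, UV and control libraries of the same number deviated together from their group means, with correlations across genes of 0.756, 0.678 and 0.188, so the numbers were taken to pair these libraries, from the data and not from the labels. The UV and control libraries numbered 3 were not each other's best match, so the pairing is unclear for them. The main fit left the pairing out, and the fit with the replicate number as a block was an alternative. The other alternatives were DESeq2 size factors, library totals without a composition factor, upper-quartile scaling, no filter, a stricter filter (a minimum of 50 counts), the Wald test of DESeq2 1.42.0, the first sequencing lane alone, a fit to the 6 libraries compared, and each library left out in turn. Antisense counts were also scaled with the sense library sizes, and lists were also tested with an estimated correlation and with fry. Filters for ribosomal and transfer RNA could not change any value, since the files hold 0 such features.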

Results

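RNA was measured in 9 cultures of Prochlorococcus MIT0604, 3 untreated, 3 treated with mitomycin C, which crosslinks DNA, and 3 exposed to a shock of short-wave UV light, which forms dimers of neighbouring bases. Each library gave between 5095136 and 11046942 counts in the sense direction of genes. On the first principal component of the sense values, which held 88.9% of the variance, the 3 mitomycin C libraries lay between 57.6 and 58.1 and the 6 others between -33.0 and -24.9. The second component, with 6.77%, separated the controls (10.9 to 16.4) from the UV libraries (-15.0 to -12.8). The comparisons ask how transcription of genes and of their opposite strands differed after each kind of DNA damage. Gene positions are in bp as the deposited tables give them, with no chromosome name, strand or build.

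After 2 h of mitomycin C, the 8 largest increases were in 3 integrase genes and in 5 genes just before 1 of them. A run of 6 adjacent genes at 625339 to 628044 rose together. Its integrase gene MIT0604_00720, which encodes a phage-type enzyme that cuts and joins DNA, went from 30.6 ± 2.90 to 14380 ± 1926 CPM (library-size scaled counts, SD, n = 3 per group), a log2 change of 8.88 ± 0.18 (SE). The 5 uncharacterised genes before it, MIT0604_00715 to MIT0604_00719, rose by 9.28 to 9.57. Integrase genes at other places rose as well, MIT0604_00163 (146645 to 147931) by 8.53 ± 0.22 and MIT0604_01883 (1571766 to 1573040) by 7.87 ± 0.23. All 11 genes of the mobile element list rose, with a median of 2.57 (camera, adjusted p = 7.1e-06, and adjusted p = 0.307 with an estimated correlation). Integrase genes resemble each other, and neighbouring genes in this run overlap, so the split of reads among them is uncertain.

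Most DNA repair and SOS genes rose with mitomycin C. Of 33 genes, 22 rose, 9 fell and 2 did not pass the threshold (camera, adjusted p = 0.0345, and adjusted p = 0.358 with an estimated correlation). RecA (MIT0604_01934), the recombinase that senses single-stranded DNA, went from 1706 ± 208 to 9452 ± 188 CPM, a log2 change of 2.47 ± 0.11. UmuD (MIT0604_00964), part of an error-prone DNA polymerase, rose by 2.96 ± 0.08, RuvB (MIT0604_01990), which moves Holliday junctions, by 3.16 ± 0.09, and a photolyase-like gene (MIT0604_01679), of the family that repairs UV dimers with light, by 3.24 ± 0.15. The SOS repressor LexA (MIT0604_01574) rose by 0.82 ± 0.13 and UvrA (MIT0604_02102), which recognises damage in nucleotide excision repair, by 0.84 ± 0.15. High light inducible genes, which encode small pigment-binding stress proteins, moved both ways, with 9 of 14 higher, 4 lower and 1 not past the threshold (camera, adjusted p = 0.167). MIT0604_01376 and its neighbour MIT0604_01375 rose by 5.75 ± 0.15 and 5.47 ± 0.15, and MIT0604_00788 by 3.68 ± 0.16. Members of this family are alike in sequence, so their separate counts are uncertain.

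Genes of photosynthesis fell with mitomycin C. So did most highly expressed genes: in the 508 genes of highest control expression the median was -1.31, with 381 lower and 74 higher. The lists were tested against all other genes, not against genes of like expression. In photosystem I all 12 genes fell, with a median of -4.02 (camera, adjusted p = 1.79e-09, and adjusted p = 0.18 with an estimated correlation). PsaC (MIT0604_01982), which holds its terminal iron-sulfur centres, went from 1782 ± 307 to 24.8 ± 1.30 CPM, a log2 change of -6.17 ± 0.16, and PsaD (MIT0604_01951), which docks ferredoxin, fell by 5.28 on the log2 scale. In photosystem II 22 of 23 genes fell and 1 rose, with a median of -3.17 (camera, adjusted p = 1.79e-09, and adjusted p = 0.307 with an estimated correlation). PsbZ (MIT0604_02031) changed by -5.90 ± 0.15 and the D1 core protein gene psbA (MIT0604_00265) by -2.21 ± 0.24, from 110200 ± 34920 to 23770 ± 4686 CPM. Of 28 genes for the cytochrome b6f complex and electron transport, 22 fell, 1 rose and 5 did not pass (camera, adjusted p = 2.47e-04, and adjusted p = 0.42 with an estimated correlation), and plastocyanin (MIT0604_00637), which carries electrons to photosystem I, changed by -3.92 ± 0.13. Of 22 antenna and chlorophyll genes 18 fell, 3 rose and 1 did not pass (camera, adjusted p = 1.61e-04, and adjusted p = 0.322 with an estimated correlation). Among these, the geranylgeranyl hydrogenase gene bchP (MIT0604_00860) changed by -4.75 ± 0.14. All 14 genes of carbon fixation and the carboxysome fell (camera, adjusted p = 4.93e-06, and adjusted p = 0.307 with an estimated correlation), with the shell protein CsoS1 (MIT0604_00603) at -4.08 ± 0.17. ATP synthase genes fell in 10 of 11 cases, 1 not passing (camera, adjusted p = 2.04e-05, and adjusted p = 0.307 with an estimated correlation), and the alpha subunit (MIT0604_01805) changed by -3.62 ± 0.11.

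Other groups were split. Sigma factor and transcription genes fell in 9 of 13 cases, rose in 2 and did not pass in 2 (camera, adjusted p = 0.0345, and adjusted p = 0.591 with an estimated correlation), with the principal sigma factor RpoD (MIT0604_00551) at -4.52 ± 0.14. Of 54 ribosomal protein genes 34 fell, 9 rose and 11 did not pass, with a median of -0.55 that became 0.11 with library totals alone, which gave 24 higher and 19 lower (camera, adjusted p = 0.0281, and adjusted p = 0.629 with an estimated correlation). L19 (MIT0604_00529) changed by -3.05 ± 0.13 and an S14-like gene (MIT0604_01570) by 3.17 ± 0.11. Replication and cell division genes fell in 16 of 25 cases, rose in 7 and did not pass in 2, with a median of -0.65 that became 0.01 with library totals alone, which gave 9 higher and 10 lower (camera, adjusted p = 0.159). Class II ribonucleotide reductase (MIT0604_00749), which makes deoxyribonucleotides, changed by -3.86 ± 0.12 and the division ring protein FtsZ (MIT0604_01624) by -1.55 ± 0.10. Chaperone and protease genes went both ways, 13 higher, 10 lower and 4 not past (camera, adjusted p = 0.612), with the co-chaperone DnaJ (MIT0604_00017) at 3.35 ± 0.08 and the unfoldase ClpX (MIT0604_02045) at -2.91 ± 0.09. The nitrogen list had 6 genes higher, 13 lower and 10 not past, with a median of -0.26 that became 0.38 with library totals alone, which gave 14 higher and 10 lower, and 0.01 with upper-quartile scaling (camera, adjusted p = 0.159). Glutamine synthetase (MIT0604_00981) changed by -2.66 ± 0.09.

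Smaller or less uniform lists did not pass the list test for mitomycin C. The oxidative stress list had 6 genes higher, 11 lower and 2 not past, or 7 higher and 8 lower with library totals alone (camera, adjusted p = 0.227), with a thioredoxin (MIT0604_01211) at -3.38 ± 0.10. The phosphate and porin list had 1 higher, 5 lower and 4 not past, with a median of -0.66 that became -0.04 with library totals alone, which gave 5 higher and 4 lower (camera, adjusted p = 0.227). In it the porin MIT0604_01766, an outer membrane channel, was at -5.67 ± 0.13. The iron and metal list had 2 higher and 5 lower (camera, adjusted p = 0.278), with flavodoxin (MIT0604_01436), an electron carrier, at -3.73 ± 0.43. The pentose phosphate and glycogen list had 2 higher, 6 lower and 3 not past (camera, adjusted p = 0.538), with transaldolase (MIT0604_00573) at -2.37 ± 0.10 and the dehydrogenase activator OpcA (MIT0604_01223) at 1.86 ± 0.08. Its median of -0.54 became 0.12 with library totals alone, which gave 5 higher and 5 lower. The 4 clock genes were too few to test, with 2 higher and 1 lower, 1 higher and 1 lower adjusted over the list alone, and 1 higher and 2 lower with DESeq2 size factors. KaiB (MIT0604_01660) changed by -2.70 ± 0.16 and CpmA (MIT0604_01590) by 1.18 ± 0.10, while the clock-associated kinase gene sasA (MIT0604_01228) was at 0.24 ± 0.10. The libraries overlapped for sasA, and its call was lost without control replicate 2 or 3 or mitomycin C replicate 1, 2 or 3, where its adjusted p was 0.0813, 0.118, 0.14, 0.0945 and 0.0568 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By that test it was also lost with DESeq2 size factors, no filter, the first lane or the 6 libraries compared (adjusted p = 0.107, 0.0501, 0.147 and 0.0516), and by the DESeq2 Wald test (adjusted p = 0.13).

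By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1727 of 2033 genes were past the threshold for mitomycin C against control, 871 higher and 856 lower, and 583 and 567 of them by more than 2-fold. The 3 libraries of each group did not overlap for 1742 genes (85.7%, where chance gives 10%). For the 18 lists tested, the counts adjusted over the list alone equalled those over all genes tested. With 1727 genes past the threshold the fold changes are relative to the TMM scaling: library totals alone moved the median log2 change by 0.64, and gave 1154 genes higher and 555 lower, and upper-quartile scaling moved it by 0.26. With library totals alone the DNA repair and SOS list had 24 higher and 5 lower, chaperones and proteases 16 and 7, cytochrome b6f 5 and 19, antenna and chlorophyll 5 and 14, and sigma factors 4 and 7. The 10 most abundant genes held 40.1% ± 2.28 of sense counts in the controls and 19.6% ± 0.478 with mitomycin C (SD, n = 3).

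**Figure D1:**
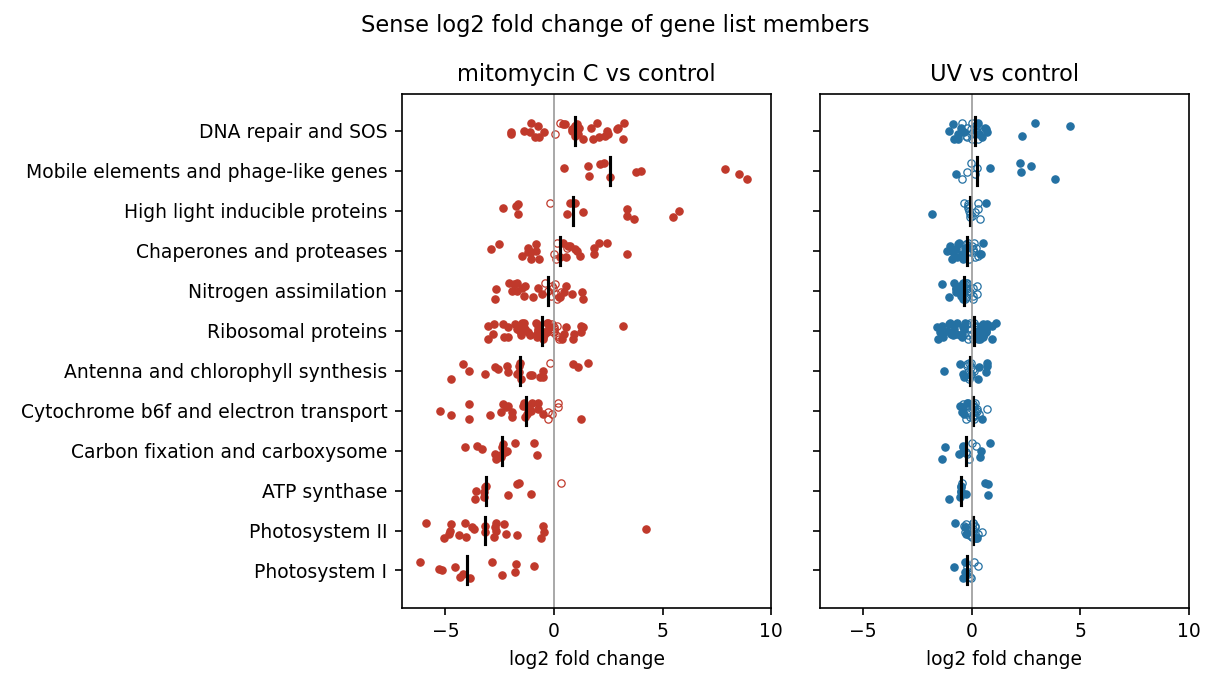
Log2 fold change of each member of 12 of the 19 gene lists for mitomycin C against control (left) and UV against control (right), from 3 libraries per group, with points for genes (filled where past the threshold) and black bars for list medians. All 12 photosystem I genes lie below 0 with mitomycin C and all 11 mobile element genes above it, while the mitomycin C medians of the ribosomal and nitrogen lists, and the UV medians of the photosystem II, antenna and high light lists, change sign with another scaling.

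The UV shock raised a small set of genes strongly. UmuD (MIT0604_00964) went from 24.2 ± 1.34 to 560 ± 12.5 CPM (SD, n = 3 per group), a log2 change of 4.54 ± 0.09 (SE), RecA (MIT0604_01934) from 1706 ± 208 to 12740 ± 599, a change of 2.90 ± 0.11, and LexA (MIT0604_01574) from 439 ± 77.7 to 2222 ± 191, a change of 2.34 ± 0.13. The largest increases were in uncharacterised genes. MIT0604_00726 (630527 to 630772) rose by 5.39 ± 0.14, and MIT0604_00778, MIT0604_00779 and MIT0604_00780, which follow each other from 678920 to 679498, by 4.74 ± 0.19, 4.71 ± 0.19 and 4.62 ± 0.20. MIT0604_00785 and MIT0604_00786, at 681365 to 681891, rose by 4.33 ± 0.16 and 4.37 ± 0.13, and MIT0604_00387 by 4.35 ± 0.12.

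Beyond these genes the DNA repair and SOS list was not uniform after UV. Of its 33 genes 9 rose, 7 fell and 17 did not pass the threshold, adjusted over the list alone 9 rose and 8 fell, with library totals alone 12 were higher and 6 lower, and with upper-quartile scaling 8 and 10 (camera, adjusted p = 0.065). UvrA (MIT0604_02102) was at 0.23 ± 0.15, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 0.264, or 0.0108 without control replicate 1 and 0.0115 with library totals alone. Of the 11 mobile element genes 5 rose, 1 fell and 5 did not pass, and adjusted over the list alone 5 rose and 2 fell (camera, adjusted p = 2.27e-04, and adjusted p = 0.474 with an estimated correlation). The site-specific recombinase MIT0604_00725 rose by 3.85 ± 0.17 and the integrases MIT0604_01883 and MIT0604_00733 by 2.72 ± 0.19 and 2.27 ± 0.12. High light inducible genes were mostly not past the threshold (1 higher, 1 lower and 12 not past, the same counts when adjusted over the list alone), with hli2 (MIT0604_01836) at -1.81 ± 0.10 (camera, adjusted p = 0.612).

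Of 27 chaperone and protease genes 13 fell, 2 rose and 12 did not pass after UV, adjusted over the list alone 14 fell, and with library totals alone 4 were higher and 11 lower (camera, adjusted p = 0.00829, and adjusted p = 0.474 with an estimated correlation). The protease subunit ClpC (MIT0604_01239) changed by -1.13 ± 0.09, HtpG (MIT0604_01001) by -1.01 ± 0.08 and DnaK (MIT0604_02094) by -0.90 ± 0.09. Of 29 nitrogen genes 13 fell and 16 did not pass, adjusted over the list alone 15 fell, and with library totals alone 7 were lower (camera, adjusted p = 0.00513, and adjusted p = 0.336 with an estimated correlation). The nitrate and nitrite transporter (MIT0604_01293) changed by -1.36 ± 0.11, glutamine synthetase (MIT0604_00981) by -1.05 ± 0.09 and the global nitrogen regulator (MIT0604_00290) by -0.80 ± 0.22. Ribosomal protein genes were divided, 20 higher, 19 lower and 15 not past, and 22 higher and 20 lower adjusted over the list alone (camera, adjusted p = 0.182). Library totals alone gave 27 higher and 18 lower, and upper-quartile scaling 21 higher and 22 lower. The adjacent genes for S8 (MIT0604_01916), L5 (MIT0604_01917) and L24 (MIT0604_01918) changed by -1.60 ± 0.10, -1.57 ± 0.09 and -1.45 ± 0.09. The median of this list was 0.10, while its mean was -0.08 and the list test pointed down. Sigma factor and transcription genes had 5 higher, 6 lower and 2 not past, and 5 higher and 7 lower adjusted over the list alone (camera, adjusted p = 0.158), with the beta prime subunit of RNA polymerase (MIT0604_01837) at -1.33 ± 0.10.

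Photosystem II had 1 gene higher, 3 lower and 19 not past after UV, 0 past adjusted over the list alone, 4 higher and 2 lower with library totals alone, and 1 higher and 6 lower with upper-quartile scaling (camera, adjusted p = 0.82), with psbA (MIT0604_00265) at -0.76 ± 0.23. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment psbA had an adjusted p of 0.0246, and of 0.092 without UV replicate 2. Photosystem I had 5 lower and 7 not past, the same adjusted over the list alone, and 1 higher and 2 lower with library totals alone (camera, adjusted p = 0.158), with PsaB (MIT0604_01877), a core subunit, at -0.80 ± 0.12. The cytochrome b6f and electron transport list had 1 higher, 5 lower and 22 not past, 1 higher and 3 lower adjusted over the list alone, 10 higher and 3 lower with library totals alone, and 1 higher and 9 lower with upper-quartile scaling (camera, adjusted p = 0.82). Antenna and chlorophyll genes had 5 higher, 4 lower and 13 not past, the same adjusted over the list alone, and 4 higher and 5 lower with upper-quartile scaling (camera, adjusted p = 0.82), with the antenna protein PcbD (MIT0604_01435) at -1.26 ± 0.30 and glutamyl-tRNA reductase (MIT0604_00868) at 0.70 ± 0.09. ATP synthase had 3 higher, 7 lower and 1 not past, and 3 higher and 8 lower adjusted over the list alone (camera, adjusted p = 0.158), with the gamma subunit (MIT0604_01804) at -1.03 ± 0.10. Carbon fixation had 3 higher, 5 lower and 6 not past, 3 higher and 6 lower adjusted over the list alone, and 4 higher and 4 lower with library totals alone (camera, adjusted p = 0.158), with the carboxysome proteins CsoS3 (MIT0604_00607) and CsoS2 (MIT0604_00606) at -1.35 ± 0.10 and -1.23 ± 0.11.

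In replication and cell division 5 genes rose, 7 fell and 13 did not pass after UV, and 5 rose and 9 fell adjusted over the list alone (camera, adjusted p = 0.841). A replicative DNA helicase gene (MIT0604_00046) rose by 1.92 ± 0.09. FtsZ (MIT0604_01624) was at -0.22 ± 0.10, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its adjusted p was 0.113, or 0.0367, 0.0443 and 0.0227 without control replicate 1, control replicate 2 or UV replicate 3. The phosphate and porin list had 1 higher, 2 lower and 7 not past, 1 higher and 3 lower adjusted over the list alone, 2 higher and 2 lower with library totals alone, and 1 higher and 4 lower with upper-quartile scaling (camera, adjusted p = 0.82), with a PhoH-like gene (MIT0604_01598) at 1.10 ± 0.09. The iron and metal list had 2 higher, 1 lower and 4 not past, the same adjusted over the list alone, and 2 higher and 2 lower with upper-quartile scaling (camera, adjusted p = 0.82), with a ferric iron transporter gene (MIT0604_01424) at -1.43 ± 0.26. The oxidative stress list had 3 higher, 2 lower and 14 not past, 2 higher and 2 lower adjusted over the list alone, and 5 higher and 1 lower with library totals alone (camera, adjusted p = 0.82). The pentose phosphate and glycogen list had 1 higher and 10 not past, 0 past adjusted over the list alone, 3 higher with library totals alone, and 1 higher and 3 lower with upper-quartile scaling (camera, adjusted p = 0.82). Among 4 clock genes 1 was higher and 1 lower, also adjusted over the list alone, and the list was too small to test. With library totals alone 1 was higher and 0 lower, and with upper-quartile scaling 0 higher and 1 lower.

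By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 734 of 2033 genes were past the threshold for UV against control, 385 higher and 349 lower, of which 63 and 53 changed by more than 2-fold. The 3 libraries of each group did not overlap for 902 genes (44.4%, where chance gives 10% if libraries are unpaired). Library totals alone moved the median log2 change by 0.11 and gave 502 genes higher and 222 lower. Upper-quartile scaling moved it by -0.05 and gave 353 higher and 444 lower. The UV medians of the photosystem II, antenna, high light, pentose phosphate, oxidative stress and clock lists lay within 0.11 of 0 and changed sign with library totals alone or with upper-quartile scaling. In photosystem II and the cytochrome b6f list the median was 0.05 and 0.06, while the mean was -0.02 and -0.01 and the list test pointed down.

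**Figure D2:**
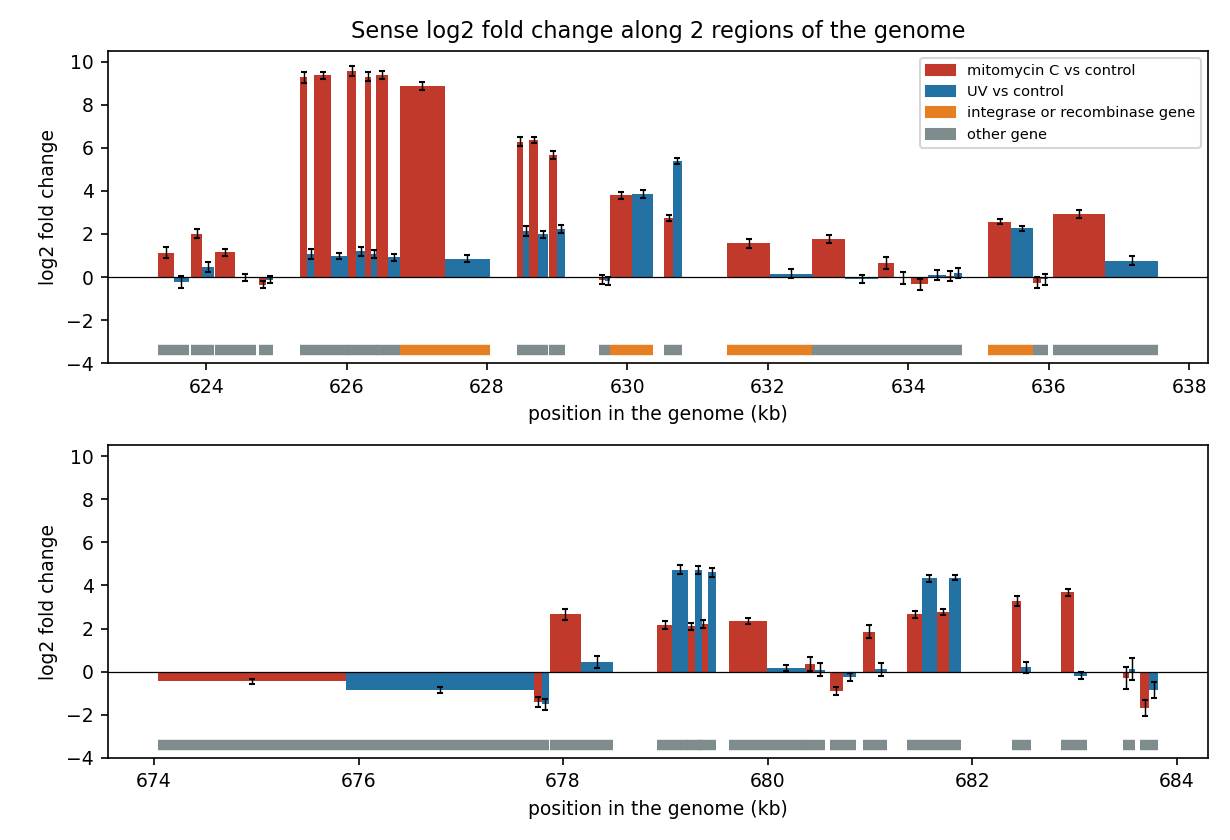
Sense log2 fold change of each gene against control along 2 regions of the genome, with position in kb on the horizontal axis, a mitomycin C bar (red) and a UV bar (blue) over each gene, standard errors from 3 libraries per group, and boxes for genes, orange for integrases and recombinases. The upper region holds the 6 genes from 625339 to 628044 that rose with mitomycin C by 8.88 to 9.57, and the lower one MIT0604_00778 to MIT0604_00780 and MIT0604_00785 and MIT0604_00786, which rose with UV by 4.33 to 4.74.

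Mitomycin C and UV were also compared with each other. UmuD (MIT0604_00964) was lower with mitomycin C than with UV, at 187 ± 8.75 against 560 ± 12.5 CPM (SD, n = 3), a log2 difference of -1.58 ± 0.07, and LexA (MIT0604_01574) differed by -1.53 ± 0.13. RecA (MIT0604_01934) differed by -0.43 ± 0.10, past the threshold with TMM scaling, but this difference became 0.11 with library totals alone and -0.10 with upper-quartile scaling, neither past the threshold. Exodeoxyribonuclease V beta and alpha chains (MIT0604_01254 and MIT0604_01253), which unwind and trim broken DNA ends, were higher with mitomycin C by 3.32 ± 0.23 and 3.12 ± 0.21, RecG (MIT0604_00856), a helicase for stalled forks, by 3.13 ± 0.09, and UvrA (MIT0604_02102) by 0.62 ± 0.15. In the DNA repair and SOS list 18 genes were higher, 12 lower and 3 not past (camera, adjusted p = 0.196). Of 11 mobile element genes 10 were higher and 1 did not pass (camera, adjusted p = 2.69e-04, and adjusted p = 0.41 with an estimated correlation), with the integrase MIT0604_00720 at 8.03 ± 0.18.

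Photosynthesis genes were lower with mitomycin C than with UV. Here too the lists were tested against all other genes, not against genes of like expression. In photosystem I all 12 genes were lower (camera, adjusted p = 8.78e-09, and adjusted p = 0.298 with an estimated correlation), with PsaC (MIT0604_01982) at -6.08 ± 0.16. In photosystem II 21 were lower, 1 higher and 1 not past, or 22 lower and 1 higher adjusted over the list alone (camera, adjusted p = 3.16e-09, and adjusted p = 0.41 with an estimated correlation), with PsbZ (MIT0604_02031) at -5.80 ± 0.15 and psbA (MIT0604_00265) at -1.45 ± 0.23. The cytochrome b6f and electron transport list had 23 lower, 2 higher and 3 not past (camera, adjusted p = 3.19e-04, and adjusted p = 0.478 with an estimated correlation), and the antenna and chlorophyll list 17 lower, 3 higher and 2 not past (camera, adjusted p = 2.12e-04, and adjusted p = 0.41 with an estimated correlation). ATP synthase had 10 of 11 lower and 1 not past (camera, adjusted p = 1.18e-04, and adjusted p = 0.41 with an estimated correlation), and carbon fixation 14 of 14 lower (camera, adjusted p = 4.11e-05, and adjusted p = 0.41 with an estimated correlation), with phosphoribulokinase (MIT0604_00887) at -3.13 ± 0.09. FtsZ (MIT0604_01624) was at -1.33 ± 0.10 and the co-chaperone genes dnaJ (MIT0604_00017) and grpE (MIT0604_00016) at 3.78 ± 0.09 and 3.02 ± 0.09.

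The other lists did not pass between the treatments. High light inducible genes had 8 higher, 3 lower and 3 not past (camera, adjusted p = 0.105), and ribosomal proteins 18 higher, 31 lower and 5 not past, or 23 higher and 25 lower with library totals alone and 22 and 26 with upper-quartile scaling (camera, adjusted p = 0.105). Sigma factors and transcription had 2 higher, 10 lower and 1 not past, or 4 higher and 5 lower with library totals alone (camera, adjusted p = 0.105). Replication and cell division had 7 higher, 16 lower and 2 not past (camera, adjusted p = 0.167), and chaperones and proteases 14 higher, 9 lower and 4 not past (camera, adjusted p = 0.196). Oxidative stress had 5 higher, 12 lower and 2 not past (camera, adjusted p = 0.197). Phosphate and porin genes had 3 higher, 5 lower and 2 not past, or 5 higher and 4 lower with library totals alone (camera, adjusted p = 0.269), and iron and metal genes 2 higher, 4 lower and 1 not past (camera, adjusted p = 0.302). Nitrogen genes had 11 higher, 12 lower and 6 not past, or 14 higher and 10 lower with library totals alone and 13 and 11 with upper-quartile scaling (camera, adjusted p = 0.576). Pentose phosphate and glycogen genes had 3 higher, 6 lower and 2 not past, or 5 higher and 5 lower with library totals alone or upper-quartile scaling (camera, adjusted p = 0.576). The medians of the ribosomal, nitrogen and pentose phosphate lists, -0.47, -0.19 and -0.39, became 0.06, 0.34 and 0.15 with library totals alone, and that of the nitrogen list 0.14 with upper-quartile scaling. Of the 4 clock genes 2 were higher, 1 lower and 1 not past, with KaiB (MIT0604_01660) at -2.62 ± 0.17, and the list was too small to test.

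By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1711 of 2033 genes were past the threshold between mitomycin C and UV, 872 higher with mitomycin C and 839 lower, of which 573 and 575 differed by more than 2-fold. The 3 libraries of each group did not overlap for 1794 genes (88.2%, where chance gives 10%). Apart from photosystem II, the counts adjusted over the list alone equalled those over all genes tested. Library totals alone moved the median log2 difference by 0.53 and gave 1102 genes higher and 603 lower, and upper-quartile scaling moved it by 0.33. With library totals alone the DNA repair and SOS list had 20 higher and 7 lower, chaperones and proteases 17 and 6, cytochrome b6f 6 and 19, antenna and chlorophyll 5 and 14, oxidative stress 7 and 9, and replication and cell division 9 and 12. The list calls depended on the test: with an estimated correlation 0 of 18 lists passed in any of the 3 comparisons. Regroupings of the libraries that mix the groups gave up to 10, 7 and 10 lists past the threshold for mitomycin C against control, UV against control and mitomycin C against UV. They divide each real group unevenly, so part of the real difference stays in them. Their counts therefore do not measure how often lists pass without an effect.

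Some genes changed in the same direction under both treatments. The site-specific recombinase MIT0604_00725 (629753 to 630370) rose by 3.78 ± 0.17 with mitomycin C and by 3.85 ± 0.17 with UV (SE, n = 3 per group). MIT0604_00963, annotated as a DNA-directed DNA polymerase and overlapping umuD at its end, rose by 3.78 ± 0.12 and 3.51 ± 0.12, and MIT0604_00387 by 3.45 ± 0.12 and 4.35 ± 0.12. MIT0604_00393 rose by 3.26 ± 0.60 and 3.99 ± 0.62, and MIT0604_01892 by 6.96 ± 0.29 and 3.04 ± 0.33. In the other direction hli2 (MIT0604_01836) changed by -1.65 ± 0.10 and -1.81 ± 0.10, and the ferric iron transporter gene MIT0604_01424 by -2.81 ± 0.27 and -1.43 ± 0.26. MIT0604_01816, MIT0604_01190 and MIT0604_01382 fell in both, by 1.54 or more on the log2 scale in each.

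Across 2033 genes, 207 were higher and 196 lower under both treatments, where independent lists would share 164.9 and 146.9, and 237 were past the threshold in opposite directions. All 237 were also past it between mitomycin C and UV, which opposite changes make likely. Of them 101 were higher with mitomycin C and lower with UV, and 136 the other way. The number of opposite calls that independent lists would give was not computed, so 237 cannot be called many or few. The log2 changes of the treatments correlated across genes (Pearson r = 0.31, Spearman rho = 0.235), but both use the same 3 control libraries, and genes are not independent replicates. Simulated unchanged groups sharing 3 controls, drawn independently although UV and control libraries of the same number deviated together, gave a median r of 0.502 (0.408 to 0.560 over 50 simulations). In them a median of 0 genes, and at most 1, were higher in both. The simulations held no treatment effect, so this count was bound to lie near 0 and is no reference for the 207. Without such effects the simulated r is set by the shared controls, so it is no reference for the observed r of 0.31 either. The covariance was 0.389 against 0.0188 in the simulations, a difference of 0.371. The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess of 207 and 196 genes over independent lists may come from the shared controls.

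**Figure D3:**
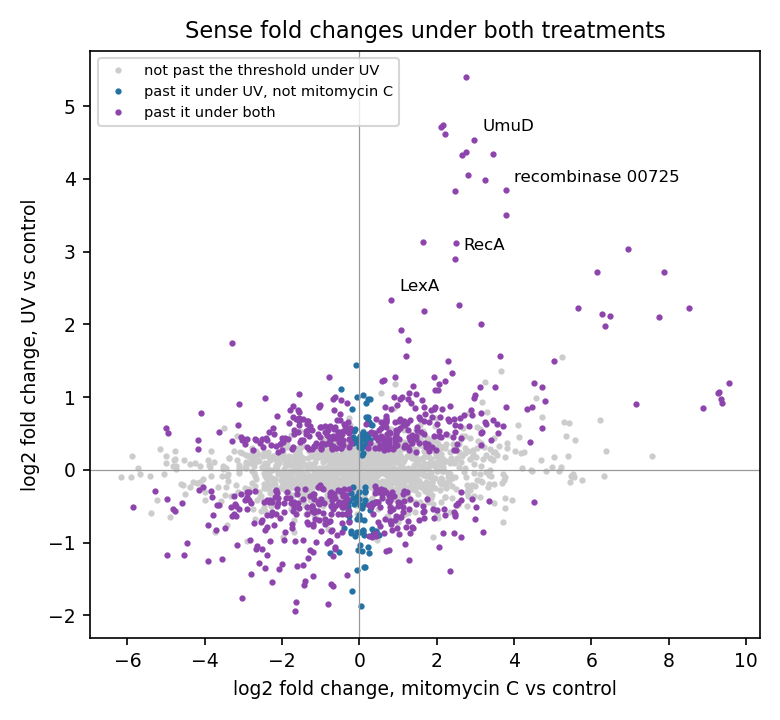
Sense log2 fold change of 2033 genes with UV (vertical) against that with mitomycin C (horizontal), both from 3 libraries per group and the same 3 control libraries, with points for genes coloured by whether they passed the threshold under UV and under mitomycin C. RecA, UmuD, LexA and the recombinase MIT0604_00725 lie in the upper right, where 207 genes were past the threshold in both.

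The share of reads from the strand opposite to genes was higher in all 6 treated libraries than in the 3 controls. It was 6.66% ± 0.827 of gene-assigned reads in the controls, 21.1% ± 0.491 with mitomycin C and 8.85% ± 0.532 with UV (SD, n = 3). The 3 mitomycin C libraries lay between 20.5% and 21.4%, and the 3 controls between 5.77% and 7.41%. The mitomycin C share exceeded the control share by 14.4 percentage points and the UV share by 12.2, and the UV share exceeded the control share by 2.19. In each comparison the libraries did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. This test left out the pairing by number that the data show for UV and control libraries. The binomial interval (Wilson, 95%) of mitomycin C replicate 3, at 21.4%, ran from 21.41% to 21.47%, and that of control replicate 1, at 5.77%, from 5.76% to 5.79%.

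**Figure D4:**
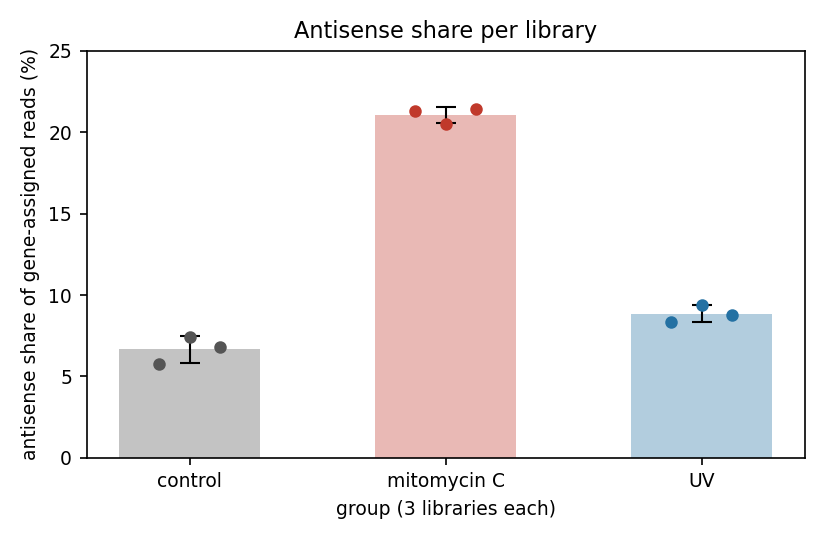
Antisense share of gene-assigned reads in percent for the 3 groups, with points for libraries, bars for group means and whiskers for the SD (n = 3). The mitomycin C libraries lie between 20.5% and 21.4%, above all 6 others.

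Within the antisense reads, single loci changed strongly. With mitomycin C the antisense counts of the integrase gene MIT0604_01883 went from 83.3 ± 32.2 to 12030 ± 197 CPM of antisense (SD, n = 3), a log2 change of 7.24 ± 0.20, and those of its neighbour MIT0604_01882 rose by 7.09 ± 0.32. Antisense of MIT0604_01380 had 0 counts in all 3 controls and 84.8 CPM with mitomycin C, at least 43-fold higher against a floor of 3 counts over the control group. Antisense of MIT0604_01316, annotated as DsrE-like, changed by -7.54 ± 0.20, that of MIT0604_01129 by -7.40 ± 0.38, and that of the guanylate kinase gene MIT0604_00519, an enzyme of nucleotide synthesis, by -6.87 ± 0.26. After UV the antisense of a DNA ligase gene (MIT0604_00781, 679622 to 680371) went from 817 ± 167 to 24970 ± 1350 CPM, a change of 4.93 ± 0.17, and that of the adjoining MIT0604_00782 rose by 5.84 ± 0.39. Both lie between MIT0604_00780 and MIT0604_00785, whose sense counts rose with UV. Antisense of an HNH nuclease gene (MIT0604_00031) rose by 3.39 ± 0.13, and that of MIT0604_00393, MIT0604_00394 and MIT0604_01158 changed by -2.07 ± 0.18, -1.85 ± 0.16 and -1.75 ± 0.33. Between mitomycin C and UV, antisense of MIT0604_01883, MIT0604_00721 and MIT0604_01686 differed by 6.61 ± 0.18, 6.31 ± 0.18 and 6.20 ± 0.40, and that of MIT0604_01129, MIT0604_00519 and MIT0604_01316 by -6.77 ± 0.37, -6.45 ± 0.25 and -6.39 ± 0.19.

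By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the antisense counts of 1567 of 1979 genes were past the threshold for mitomycin C against control (835 higher, 732 lower), of 379 for UV against control (189 higher, 190 lower) and of 1545 for mitomycin C against UV (816 higher, 729 lower). Libraries did not overlap for 1573, 621 and 1651 genes (79.5%, 31.4% and 83.4%, where chance gives 10% if libraries are unpaired). The UV count was 237 without UV replicate 3 and 243 without control replicate 3. These directions are relative to other antisense counts. Scaled by the sense library sizes, the counts were 1741 (1531 higher, 210 lower), 796 (741 higher, 55 lower) and 1658 (1381 higher, 277 lower), and with antisense totals alone the UV count was 387 (251 higher, 136 lower). Totals alone moved the antisense median by 0.28 for mitomycin C against control and by 0.19 for mitomycin C against UV.

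In the authors' deposited tables, 1724 sense genes had an adjusted p under 0.05 for mitomycin C against control, 756 for UV against control and 1695 for mitomycin C against UV, and 1548, 397 and 1535 antisense genes. In the authors' deposited tables, the log2 changes of all matched genes, 2033 in sense and 1979 in antisense, correlated with the edgeR values at 0.997 or more in each of the 6 tables, and 0 genes were called in opposite directions.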

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

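The tests of the antisense share and of the trend with expression were planned before their results were seen, except for the comparison of the lowest antisense density with the density needed, which was chosen after. Reads falling on more than 1 gene, which no gene count includes, made up 3.39% of aligned reads on average with mitomycin C and 2.30% in the controls (exact permutation p = 0.1, the smallest possible). Reads that were not aligned, also outside the gene counts, made up 2.82%, 3.14% and 4.50% in the 3 UV libraries, 3.48% on average, and 2.53% on average in the controls (exact permutation p = 0.1).

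The antisense share was 21.1% with mitomycin C and 6.66% in the controls. Loss of strand information in the library would put the same fraction of each gene's sense reads on the opposite strand, but at least 68.64% of sense reads lay in genes with under 50% of the rate needed, which argues against it as the whole cause. Genomic DNA would cover genes evenly, and in each mitomycin C library at least 18.22% of genes had under 25% of the antisense density that the excess needs. This lies between the bounds of 5% and 25% set beforehand, so DNA may account for part of the excess and stays open, although the antisense density at the 5th percentile of genes was only 10.2% to 11.4% of that needed. A change in antisense transcription under mitomycin C was not tested separately and also stays open.

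Log2 changes with mitomycin C fell as control expression rose (Spearman rho = -0.55 across 2033 genes, which are not independent replicates), from a median of 1.28 in the 509 genes of lowest expression to -1.31 in the 508 of highest. With expression taken from the UV libraries rho was -0.487. UV and control libraries numbered 1 and 2 deviated together, so UV expression is not free of the noise of the controls. This test therefore cannot decide how far noise of the control libraries on both axes adds to the trend. UV log2 changes, which also have the controls on both axes, had a rho of -0.117 with control expression. Their medians were 0.07 and -0.05 in the same 509 and 508 genes, although the shared deviations may lower these values. The biological coefficient of variation was 13.3%, small beside medians of 1.28 and -1.31. These values argue against control noise as the cause of the whole trend. With a uniform floor of reads taken off the mitomycin C libraries rho was -0.467, so such a floor does not account for the whole trend, and 1725 genes were past the threshold. The medians moved by like amounts in opposite directions at the low and high ends of expression. Because fold changes are relative to the scaling, the trend cannot tell a loss of abundant transcripts from a rise of rare ones. Neither was tested by itself.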

How the results depend on the processing

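Of the alternatives run on the counts, list results, shares and correlation of the comparisons, 153 stayed within their limits and 13 did not. Counts had to stay within 1.5 times the total reported, the correlation within its spread, and share differences had to keep their sign. Totals can hold while calls change. For mitomycin C against control, sense library sizes gave 1741 antisense genes (1531 higher, 210 lower), sharing 1045 of 1567 calls. Library totals alone gave 1709 sense genes (1154 higher, 555 lower), sharing 1426 of 1727 calls, and DESeq2 size factors shared 1706. The antisense count for UV against control, 379, was 214 with the first lane alone (1754 genes tested, from fewer reads) and 210 with the 6 libraries compared (1849 genes tested), for which the cause was not tested. With the sense library sizes it was 796 (741 higher, 55 lower). That scaling does not take out the higher antisense share of the UV libraries, 8.85% against 6.66% in the controls. The count ran from 237 to 542 with 1 library left out. Lists past the threshold went from 10, 3 and 7 (mitomycin C against control, UV against control, mitomycin C against UV) to 0, 0 and 0 with an estimated correlation and to 18, 6 and 18 with fry, which does not compare a list with other genes, and the cause was not tested. The correlation of the responses ran from 0.279 without UV replicate 2 to 0.353 without control replicate 2, and the cause was not tested. With 1 library left out, sense counts ran from 1660 to 1764, 572 to 955 and 1626 to 1659, antisense counts from 1480 to 1613 (mitomycin C against control) and 1451 to 1507 (mitomycin C against UV), lists from 10 to 10, 3 to 4 and 7 to 7, and differences in antisense share from 13.98 to 14.8, 1.746 to 2.564 and 11.98 to 12.51 percentage points. With the replicate number as a block the sense counts were 1769, 863 and 1743 and the antisense counts 1590, 455 and 1574. Of 231 results for named genes, 212 kept their direction and side of the threshold under every alternative run; over 3499 alternatives 60 lost the call, 5 gained it and 1 reversed. The reversed one was RecA between mitomycin C and UV, 0.11 with library totals alone, a scaling that moved the median of all genes in that comparison by 0.53. Of genes changed 2-fold in simulated counts, 91%, 88.1% and 92.5% were recovered in sense and 91%, 74.6% and 92.5% in antisense (mitomycin C against control, UV against control, mitomycin C against UV).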

Other observations

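The tests on neighbours of mobile element genes were chosen only after the result was seen, while the regroupings of libraries were planned. The genes in this paragraph were also chosen after their values were seen. Near the integrase MIT0604_00163, MIT0604_00164 rose with mitomycin C by 7.76 ± 0.21 (SE, n = 3 per group) and the zinc finger gene MIT0604_00161 by 7.16 ± 0.23. Further along from the integrase MIT0604_01883, which ends at 1573040, a DNA invertase-like gene (MIT0604_01887, from 1575876) rose by 5.34 ± 0.17, an exonuclease gene (MIT0604_01890, from 1576840) by 5.21 ± 0.19 and MIT0604_01897 (from 1580001) by 6.21 ± 0.20. With UV, MIT0604_01890 was at 0.03 ± 0.20 and MIT0604_01897 at 0.68 ± 0.26, not past the threshold. Another integrase, MIT0604_01303, rose by 4.02 ± 0.15 with mitomycin C and was at 0.26 ± 0.15 with UV, not past the threshold.

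Several genes outside the fixed lists, also chosen after their values were seen, rose with both treatments. MIT0604_01396, annotated as translation initiation factor IF-1, rose by 3.13 ± 0.08 with UV and 1.63 ± 0.08 with mitomycin C, and the adjoining MIT0604_01397 by 4.05 ± 0.40 and 2.81 ± 0.38. MIT0604_00394 rose by 3.11 ± 0.10 and 2.51 ± 0.09. MIT0604_00030 rose by 3.84 ± 0.40 and 2.48 ± 0.39, while the HNH nuclease gene next to it, MIT0604_00031, changed by -1.59 ± 0.17 and -1.42 ± 0.16.

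Of 84 tested genes within 5 genes of a mobile element gene, 54 rose and 20 fell with mitomycin C, with a median log2 change of 1.33. Shifting the positions along the gene order gave a median as high in a share of 0.00391 of placements (2046 shifts, highest 1.59), so placement beside these genes may account for the rise, as a hypothesis found in the same data. The shifts did not match genes by expression, and the 509 genes of lowest control expression had a median of 1.28. Whether the neighbours rose beyond genes of like expression was not tested. With UV the median was 0.10 and the share 0.101, which leaves it open. More copies of the elements' DNA in the RNA would raise both strands alike, and the ratio of antisense to sense gain over the 54 risen neighbours had a median of 0.12 (0.114 to 0.135 in the 3 libraries) with quartiles of 0.0255 and 1.23. For 21 of them it was 0.5 or more, so the spread over genes leaves this explanation open, as it does overlap with transcripts of the opposite strand, which was not tested.

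Of the 10 ways to divide the 6 libraries of a comparison into groups of 3, 1 is the real one, so a share under 0.05 is impossible. The genes past the threshold in the real division and the highest of the others were 1727 and 0, 734 and 1, and 1711 and 0 in sense (mitomycin C against control, UV against control, mitomycin C against UV), and 1567 and 0, 379 and 0, and 1545 and 0 in antisense, so 1 of 10 divisions gave as many in each. Among the 4 divisions that part all 3 numbered pairs of UV and control libraries, the highest other was 0. Every other division mixes libraries of both real groups, so the difference between them enters the spread within groups. Counts near 0 were therefore bound to result, and these gene counts cannot test chance. For lists the real and highest other counts were 10 and 10, 3 and 7, and 7 and 10, and 5, 3 and 8 of the 10 divisions gave as many. The other divisions split each real group unevenly, so part of the real difference stays in them. These list counts do not measure how often lists pass without an effect.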
